A study of Arabidopsis thaliana with 6 samples.

How the data were processed

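Seedlings of Arabidopsis thaliana, accession Col-0, were profiled on Affymetrix ATH1 arrays, with 6 groups of 1 array each: wild type and the AtrbohB mutant at 20, 30 and 40 °C. Each sample pooled 90 plants, per the labels. The deposited value table holds probe-set intensity on a linear scale. The mean of each column, without its highest and lowest 2% of values, is 100, which shows that the authors scaled the arrays to a common level. The summary method and software behind the deposited intensity are not stated in the labels or the file header.

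The table holds 22810 probe sets. Control probe sets were left out (64), which leaves 22746. The platform annotation gives 1 gene for 13513 probe sets, several genes for 503 and lists no gene for 8730; only those with 1 gene were named. Names were updated by gene number through the RefSeq table of assembly TAIR 10.1, which matched 13436 of them and did not match 77. Where a gene had several such probe sets, the one with the highest mean stood for the gene.

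Values were raised to a floor of 13.7, the 25th percentile of all 6 arrays pooled, and put on the log2 scale; 18227 probe sets above the floor on at least 2 arrays were tested. The floor is not a detection limit, and a change of a gene that lies at the floor in a group is given as at least that fold. Changes were tested with limma 3.58.1 in R 4.3.3, with genotype and temperature as additive terms, a variance prior that follows mean expression (eBayes with trend, 6.08 prior degrees of freedom) and Benjamini-Hochberg adjustment over all probe sets per comparison. Tests were two-sided and called at an adjusted p under 0.05. With 1 array per group, the 2 residual degrees of freedom hold the departure from additivity together with the array noise. A temperature effect therefore compares 2 arrays with 2, and the genotype effect 3 with 3. The difference between the genotypes in their response to temperature has no test here and is given by size. The number of arrays limits the precision of all values.

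Before the data were examined, 20 gene lists with 324 genes were fixed. For 54 of these genes the annotation lists a probe set of that gene alone, and only such genes are called measured here. The others may lie among the probe sets without a listed gene. Of the 21 heat shock factors, 0 had a listed probe set, so that list was not tested. Lists with at least 4 measured genes were tested with limma's camera (inter-gene correlation preset at 0.01, or estimated from the residuals), over 24 tests. For single arrays, the median of a list was ranked among 10000 random lists of the same size, drawn from 20 bins of mean expression. A further 25 groups, the organelle genomes, the pseudogenes and gene families by the start of their symbols, were formed after the data were seen and gave 100 tests. The named genes followed a rule set beforehand. At 40 against 20 °C they are the 10 called genes with the largest rise and the 10 with the largest fall among those of 1 direction in both genotypes. At 30 against 20 °C and at 40 against 30 °C, 6 and 6 were taken likewise. For mutant against wild type, the 10 and 10 of 1 sign at all 3 temperatures with the largest smallest difference were named. For the difference between the genotypes in the response to 40 °C, the 8 largest each way were named among genes that reached 4 times the floor on at least 1 array. Up to 4 members of each list were named by size.

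The alternatives were quantile normalization, centring on the median before the floor, a floor at the 40th percentile, no floor and no filter, log2(value + 16), a filter of all 6 arrays above the floor, limma without the trend or with a robust prior, and each array left out in turn, which leaves 1 residual degree of freedom. Each genotype alone was also counted at 2-fold. The model was tested on simulated arrays with 200 changed probe sets among 18227, far fewer than were called between temperatures. Their noise was independent and drawn from the fitted variances, without a floor or a genotype by temperature difference. The shares below hold for such arrays and do not give the share of false calls in the real data. For 40 against 20 °C, 56% of changes of 1 on the log2 scale and 99% of changes of 2 were recovered, and 6.06% of the calls were false; for mutant against wild type these shares were 67%, 99% and 2.35%. Figures were drawn with matplotlib 3.10.9.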

Results

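The series addresses how the respiratory burst, the release of reactive oxygen by NADPH oxidases, takes part in thermotolerance. It compared seedlings of wild type with a mutant that carries a dSpm transposon in AtrbohB (At1g09090), which encodes an NADPH oxidase homologue. Plants were kept on distilled water at 1 of 3 temperatures, 20, 30 or 40 °C; the length of the treatment is not given in the labels. There were 6 arrays, 1 for each genotype and temperature, so no group has replicates. Median signals lay between 38.5 and 44.0, and 22.9% to 27.6% of probe sets were at the floor of an array. The annotation names no probe set for the disrupted gene, so its level in the mutant was not analysed here. The title of the mutant array at 40 °C marks it as a repeat, without saying of what.

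At 40 against 20 °C, the 10 named genes with the largest rise included small heat shock proteins and genes of the mitochondrial genome. AT1G53540, a small heat shock protein at the floor on both 20 °C arrays, rose at least 227-fold, from signals of 13.0 in wild type and 7.3 in the mutant to 3252 and 2965. The small heat shock proteins AT2G29500, AT5G37670 and ATHSP22.0 rose by 6.56 ± 0.11, 5.59 ± 0.13 and 5.33 ± 0.17 on the log2 scale (SE, 2 arrays against 2). The mitochondrial genes nad6, nad5 and nad4L, subunits of respiratory complex I, rose by 6.81 ± 0.13, 6.02 ± 0.12 and 5.03 ± 0.15. The nuclear locus AT2G07777 rose by 5.23; chromosome 2 carries a large copy of mitochondrial DNA, so the source of this signal is uncertain. AT5G10695 rose by 5.44, and AT1G21550, at the floor on both 20 °C arrays, rose at least 33.7-fold.

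The largest falls at 40 against 20 °C took in MTP11, a manganese transporter, at -2.78 ± 0.11, and DRT100, a leucine-rich repeat protein, at -3.04 ± 0.20. AT5G19120, AT1G60590 and AT2G27420 fell (-3.14, -3.03 and -3.03), as did AT1G68440, AT4G38660 and AT1G62790 (-2.94, -2.85 and -2.81), the last to the floor on the mutant array. AT4G13580 and AT2G41770 ended at the floor on both 40 °C arrays, with fitted values of -3.60 and -3.08; these values are limits. AT2G41770 was no longer called without wild type at 40 °C (adjusted p = 0.0564) or without the mutant at 40 °C (adjusted p = 0.0556). In all, limma called 5130 probe sets, 2456 higher and 2674 lower, and 700 and 1090 of these differed at least 2-fold. The smallest adjusted p was 1.78e-08. Centring the arrays on their medians gave 1737 higher and 2907 lower. The count fell to 822 without wild type at 40 °C, 985 without the mutant at 40 °C, 1787 without wild type at 20 °C, 1926 without the mutant at 20 °C, 2777 without wild type at 30 °C and 2800 without the mutant at 30 °C.

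Of the 6 lists fixed beforehand that could be tested, the small heat shock proteins stood out at 40 °C. Of 8 measured members, 7 rose, with a median of 4.61, and 7 did so adjusted over the list alone; camera gave an adjusted p of 2.97e-09, and adjusted p = 0.408 with an estimated correlation. AT4G21870 had -0.30. Of 6 measured chaperones, 5 rose, and the same number adjusted over the list alone, among them AT5G48570 (4.68), Hop3 (4.34), AT2G20560 (2.62) and Hsp70-2 (1.49). The chaperone list had a median of 2.06 and a camera adjusted p of 1.53e-05, and adjusted p = 0.533 with an estimated correlation. AT4G28480, a DnaJ homologue, had -0.06. In single arrays, the median of the small heat shock proteins was 4.63 in wild type and 4.64 in the mutant, above all 10000 random lists in both.

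The 15 measured genes of the mitochondrial genome, grouped after the data were seen, all rose at 40 against 20 °C, with a median of 4.22. They include cox1 (4.49), cox2 (4.88), nad1 (4.38) and nad9 (4.22); ccb203 was at the floor at 20 and 30 °C and rose at least 24.5-fold. The camera adjusted p was 2.74e-17, and adjusted p = 0.932 with an estimated correlation. The median stayed above 4 with quantile normalization (4.18) and with centring (4.15). The median was 4.37 in wild type and 4.06 in the mutant. The 69 genes of the plastid genome had a median of 0.31, with 26 higher and 8 lower; with quantile normalization these were 0.08, 7 and 8, and with centring 0.24, 3 and 8.

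Members of other lists also changed at 40 °C. The chloroplast cold protein COR15A (2.34), the dehydrin COR47 (0.62) and the auxin conjugating enzyme GH3.3 (0.70) rose, and the expansin EXPA4 fell (-0.98). Among 5 oxidative stress genes, STZ, a zinc finger repressor, rose by 3.15 and WRKY53 by at least 1.34; GSTU25 had 0.38 and AT2G21640 had -0.43. WRKY53 was at the floor at 20 °C and was not called at 30 or 40 °C with the higher floor. Adjusted over the list alone, 2 of the 5 rose. Among 4 enzymes that scavenge reactive oxygen, GR1 (glutathione reductase) fell by 0.59, and the thylakoid ascorbate peroxidase TAPX rose by 0.42, a call lost on centring; the list alone gave 1 lower and 1 higher. Of 5 photosynthesis genes, LHCB4.2 (0.70), LHCB4.1 (0.63) and RCA (0.41) rose, 3 adjusted over the list alone, and RCA was lost on centring. The camera adjusted p of the photosynthesis list was 0.0457, and adjusted p = 0.738 with an estimated correlation. With quantile normalization its median went from 0.41 to -0.05, and only LHCB4.2 of the 3 was called. The reference genes GAPC2 (0.42) and AT4G26410 (0.33) rose, 2 of 5 adjusted over the list alone, and centring ended both calls. IAA29, an auxin response gene at the floor in wild type at 20 °C, rose by at least 0.78, and the lactate dehydrogenase AT4G17260 by 0.53, a call lost on centring. The root marker PYK10, a beta-glucosidase of endoplasmic reticulum bodies, fell by 1.69, while the root hair genes EXPA7 and EXPA18 had -0.32 and 0.24.

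**Figure D1:**
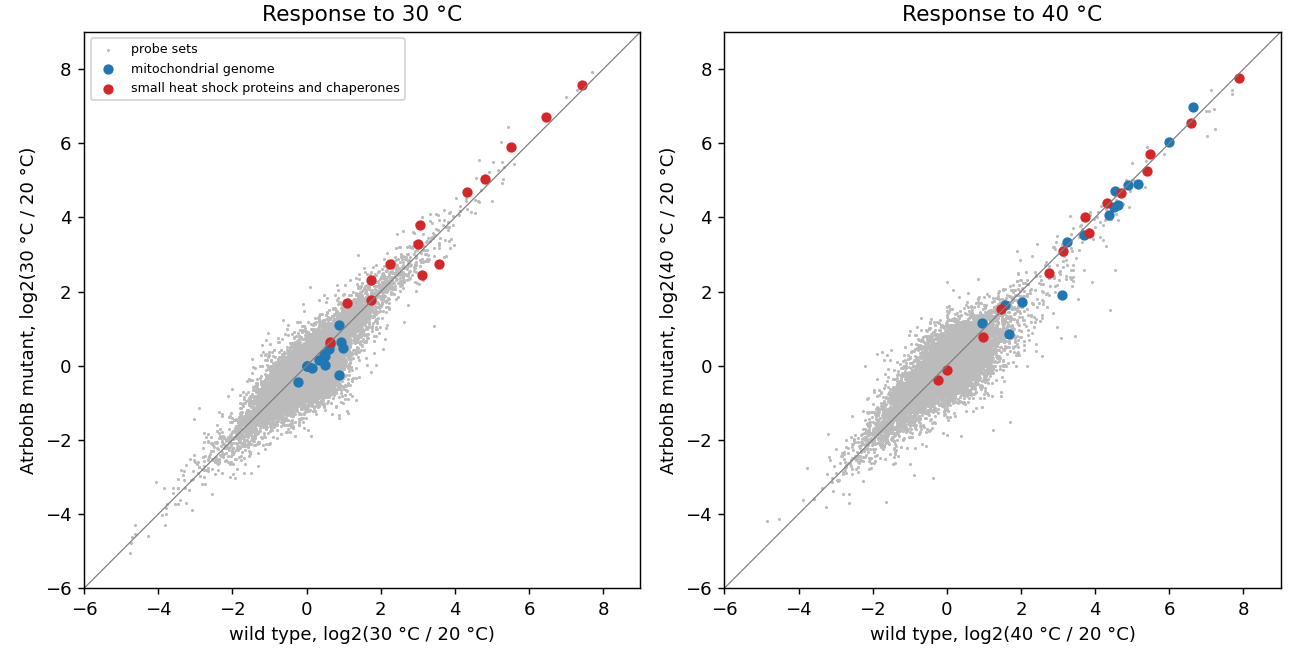
Response of each probe set to 30 °C (left) and 40 °C (right) against 20 °C as log2 ratios of single arrays, wild type on the x axis and the AtrbohB mutant on the y axis, with the diagonal in grey. Red points are the small heat shock proteins and chaperones, and blue points the 15 mitochondrial genes, whose median at 40 °C was 4.37 in wild type and 4.06 in the mutant.

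At 30 against 20 °C, small heat shock proteins and chaperones had already risen. AT1G53540 rose at least 183-fold, AT2G29500 rose by 6.59 ± 0.11, and AT5G48570, a co-chaperone of the FKBP family, by 5.70 ± 0.12. AT1G15010 rose by 5.94 ± 0.32, AT5G10695 by 5.64 ± 0.18, and AT5G05600, a jasmonate oxidase, by 5.26 ± 0.16. AT1G47400, an IRON MAN peptide of iron uptake, fell (-4.91 ± 0.16), as did AT1G06000, a flavonol rhamnosyltransferase (-4.06 ± 0.15). AT1G60590, AT2G27420 and AT5G42760 had -4.67, -4.59 and -4.43, and AT5G20790 dropped to the floor on both 30 °C arrays, with a fitted value of -4.76 as a limit. Of 6480 called probe sets, 2711 were higher and 3769 lower, and 1310 and 1235 of them differed at least 2-fold. Centring gave 3001 higher and 3153 lower. The count was 2089 without the mutant at 30 °C, 2781 without wild type at 30 °C, 3150 without wild type at 20 °C and 3332 without the mutant at 20 °C.

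All 8 measured small heat shock proteins rose at 30 °C, with a median of 3.29 and all 8 adjusted over the list alone (camera adjusted p = 2.92e-11, and adjusted p = 0.408 with an estimated correlation). All 6 chaperones rose as well, with all 6 adjusted over the list alone and a median of 1.90 (camera adjusted p = 4.02e-07, and adjusted p = 0.533 with an estimated correlation). COR47 rose by 2.43 and COR15A by 3.09. GH3.3 and WES1, another auxin conjugating enzyme, rose by 2.56 and 0.89. Of the stress genes of the endoplasmic reticulum, BZIP28 rose by 1.58 and BZIP60 had -0.02. ATERDJ3B, a DnaJ protein of that compartment, rose by 0.90. The defensin PDF1.2, at the floor at 20 °C, rose by at least 1.45.

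Of 4 measured enzymes that scavenge reactive oxygen, 3 fell at 30 °C. SAPX, the stromal ascorbate peroxidase, fell (-1.27), as did the glutathione reductases GR1 (-0.96) and GR (-0.61); TAPX had -0.05. This list of 4 had a median of -0.78, with 3 lower adjusted over the list alone, and a camera adjusted p of 0.0503, which is not a call. GSTU25, a glutathione transferase, fell by 1.86, while WRKY53, at the floor at 20 °C, rose by at least 1.18 and WRKY6 by 0.72; the list alone gave 3 higher and 1 lower. Expansins EXPA8 (-1.69) and EXPA4 (-0.75) fell. The photosynthesis genes PRK (-0.41) and SBPASE (-0.33) fell, both also adjusted over the list alone, calls that centring ended. The clock gene GI had 0.04 at 30 °C and rose by 0.85 at 40 °C.

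Between 30 and 40 °C, 5 of the 6 named genes with the largest rise belong to the mitochondrial genome. nad6, nad5 and cox1 rose by 5.83, 5.49 and 4.82, and cox2 by 4.28. AT4G27657 rose by 4.65, from signals of 17.6 in wild type and 14.1 in the mutant at 30 °C to 464.6 and 336.1. The expansin-like genes EXLA1 (-5.13) and EXLA2 (-5.22) fell, and so did EXO (EXORDIUM, -5.09), a growth gene of brassinosteroid signalling. GAT1_2.1, a glutamine amidotransferase, had -5.23 and AT5G62360 -5.17, and AT2G38240, a jasmonate oxidase, fell by 5.00; GAT1_2.1, EXLA2 and AT5G62360 reached the floor on 1 array at 40 °C. These 6 had risen by 3.07 to 5.17 at 30 against 20 °C; the wild-type signals of EXO, for example, were 305.4 at 20 °C, 2600 at 30 °C and 115.0 at 40 °C.

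Of the 6 lists fixed beforehand that could be tested, none was called by camera between 30 and 40 °C, though single members changed. The 4 scavenging enzymes rose from 30 to 40 °C by 0.37 to 1.15, with 4 adjusted over the list alone (camera adjusted p = 0.0536, not a call); 2 of these rises, GR1 and TAPX, were lost on centring. Of the small heat shock proteins, 3 rose, among them ATHSP22.0 (2.56) and AT5G37670 (2.44), and 2 fell, AT4G21870 (-2.81) and AT5G51440 (-1.39); the rise of AT1G53540 (0.31) was lost on quantile normalization and on centring. Adjusted over the list alone, 5 rose and 2 fell. Of the chaperones, 4 fell and 1 rose, with the same numbers adjusted over the list alone. Across all probe sets, limma called 4538 higher and 3243 lower, and the median of all changes was 0.15. Centring brought that median to 0.03 and the calls to 3214 higher and 3817 lower. The count of 7781 fell to 2783 without the mutant at 40 °C, 3180 without the mutant at 30 °C, 3306 without wild type at 40 °C and 3986 without wild type at 30 °C.

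**Figure D2:**
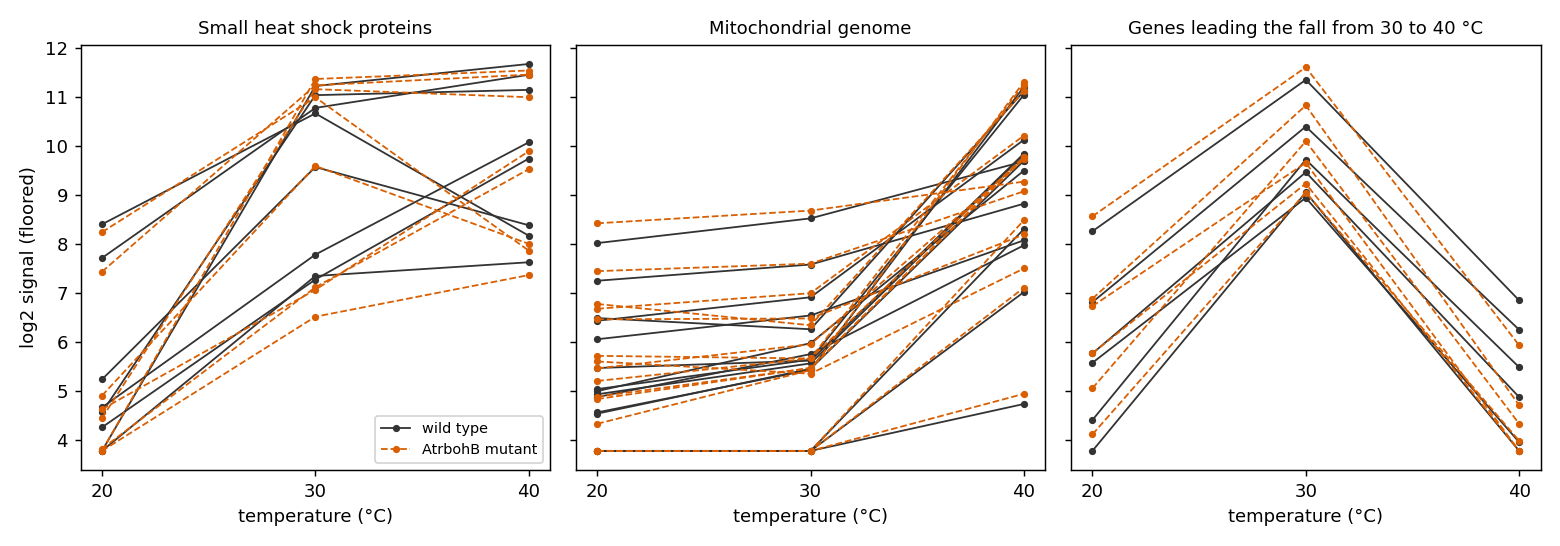
Log2 signal on each array at 20, 30 and 40 °C for the 8 small heat shock proteins (left), the 15 mitochondrial genes (middle) and the 6 genes with the largest fall from 30 to 40 °C (right), with a line per gene and genotype (wild type solid, mutant dashed); values at the bottom lie at the floor. In both genotypes the mitochondrial genes leave their 20 °C level mainly between 30 and 40 °C, where their median change was 3.65.

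The responses to 30 and 40 °C overlapped in part. Of the called probe sets, 782 were higher and 1291 lower at both temperatures, against 365.3 and 552.9 for independent lists. Another 355 rose at 30 °C and fell at 40 °C and 292 did the reverse, against 397.7 and 507.9. These comparisons share the 20 °C arrays, so part of the excess may come from them. Simulated arrays without any effect gave a covariance of 0.0385 between the responses, against 0.262 in wild type and 0.194 in the mutant. Their correlation was 0.436, against 0.431 in wild type and 0.327 in the mutant. The correlation within a genotype therefore does not separate an overlap from the shared array. Other pairs share no array. The 30 °C response of wild type and the 40 °C response of the mutant had r = 0.296 and covariance 0.171. Mutant at 30 °C and wild type at 40 °C had 0.327 and 0.204. Probe sets are not independent replicates. At 2-fold the first pair shared 196 higher and 309 lower, against 59.5 and 75.4 for independent lists. The second pair shared 301 and 387, against 74.9 and 99.1. Opposite directions were held by 95 and 36 in the first pair and 78 and 21 in the second. An overlap is thus also seen without a shared array. Between genotypes, the responses to the same temperature had r = 0.871 at 30 °C and 0.829 at 40 °C across 18227 probe sets.

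No gene passed the test between mutant and wild type over the 3 temperatures. QQS, an Arabidopsis gene that affects starch content, came nearest: it was higher in the mutant by 1.18 at 20 °C, 1.19 at 30 °C and 1.07 at 40 °C, with signals of 41.4, 45.5 and 75.9 in wild type and 93.6, 103.5 and 159.2 in the mutant (limma adjusted p = 0.278). QQS was called with the filter on all 6 arrays (adjusted p = 0.0209) and on log2(value + 16) (adjusted p = 0.0242). Also named were AT5G15780 (0.84), AT3G42700 (0.70), AT5G38780 (0.52) and AT5G01080 (0.78), all with an adjusted p of 0.978; these values are limits, as AT3G42700 was at the floor on all 3 wild-type arrays and the others on 1. On the lower side, AT2G18410 had -0.82, AT3G62260, a protein phosphatase, -0.58, AT5G37590 -0.62 and AT4G11210 -0.67, with the same adjusted p. UGT71C1, a glucosyltransferase, had -0.58.

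The other named genes differed by 0.46 to 0.68, with 1 exception. On the higher side these were AT5G35640, AT2G30680, AT1G80450, AT5G67350 and AT5G01910; on the lower side they were AT1G19340, AT5G04460, AT3G03000 and AT1G63740, and AT5G11600 had -0.72. Of these, AT1G80450, AT1G19340, AT1G63740 and AT5G11600 were at the floor on 1 array. limma called 0 of 18227 probe sets, with 735 at an unadjusted p under 0.05, which is 4.03% of those tested. The small heat shock proteins had a median of -0.14 in the mutant, with no member called (camera adjusted p = 0.0360, and adjusted p = 0.533 with an estimated correlation). That median was -0.14 at 20 °C, 0.07 at 30 °C and -0.20 at 40 °C, at percentiles 2.41, 78.7 and 1.16 of the random lists. The photosynthesis genes had a median of 0.13, with no member called (camera adjusted p = 0.0457, and adjusted p = 0.738 with an estimated correlation), and quantile normalization turned their mean from 0.11 to -0.03. Of the oxidase family itself, AT1G19230 had 0.08 and AT4G25090, at the floor at 30 and 40 °C, had -0.22 in the mutant. Medians of the other tested lists were -0.06 for the chaperones, -0.01 for the scavenging enzymes, -0.11 for the oxidative stress genes and 0.06 for the reference genes. The chaperone median changed sign between temperatures: -0.15 at 20 °C, 0.19 at 30 °C and -0.21 at 40 °C. These lay at percentiles 2.23, 98.3 and 1.85 of the random lists, from single arrays. The random lists hold genes drawn singly, so a list whose genes vary together reaches extreme percentiles more easily. The correlation estimated from the residuals was 0.715 for the chaperones and 0.0766 for the small heat shock proteins.

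The genotypes differed most at 40 °C. At that temperature 84 probe sets were at least 2-fold higher and 199 at least 2-fold lower in the mutant, against 71 and 43 at 20 °C and 26 and 91 at 30 °C. Of the genes named for the difference in response, the lower side was as follows: the response to 40 °C of the mutant minus that of wild type was -2.33 for AT1G77640, an AP2/ERF factor, -2.32 for CML37, -2.15 for AT3G01830 and -1.95 for CML38, the last 3 being calmodulin-like genes. CML38 had signals of 316.1 in wild type and 82.1 in the mutant at 40 °C, and 117.1 and 129.7 at 30 °C. GAT1_2.1, AT1G79470, AT2G38240 and AT2G07776 had differences of -2.06, -1.88, -1.80 and -1.75. The other way, AT1G63240 had 2.25, THO7, of the THO complex of mRNA export, 2.22, and AT1G60730 2.13. AT1G34630, AT4G10270, AT3G16990, AT3G20300 and AT1G76070 followed with 1.94, 1.85, 1.68, 1.67 and 1.61. These values depend on the floor where an array lies at it at 20 or 40 °C: AT1G63240, THO7 and AT3G16990 in wild type at 40 °C, AT3G01830 and GAT1_2.1 in the mutant at 40 °C, AT2G07776 in wild type at 20 °C, and CML37, CML38 and AT3G01830 in both genotypes, and AT1G63240 in wild type, at 20 °C.

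With 1 array per group these differences have no test. Those of AT2G07776 and AT1G76070 come mainly from the 20 °C arrays. Mutant minus wild type was 1.51 at 20 °C and -0.23 at 40 °C for AT2G07776, and -1.15 and 0.455 for AT1G76070. The log2 change to 40 °C in the mutant minus that in wild type was at least 2 (4-fold) upward for 4 probe sets and downward for 15, whichever way each genotype changed. At 30 °C the numbers were 1 and 9. At 2-fold they were 217 and 421 at 40 °C and 100 and 485 at 30 °C, with SDs of 0.432 and 0.414 over all probe sets. In place of 19 in all, the higher floor gave 6. With it the values fell in size to 0.39 for AT3G20300, 0.66 for AT3G16990, 0.99 for AT1G76070, 1.19 for THO7, -0.72 for AT2G07776, -0.93 for AT2G38240, -1.04 for GAT1_2.1, -1.13 for AT3G01830 and -1.18 for AT1G79470. Without any floor CML37 had 1.29, AT1G63240 -0.42, AT3G01830 -5.46 and AT2G07776 -2.56.

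**Figure D3:**
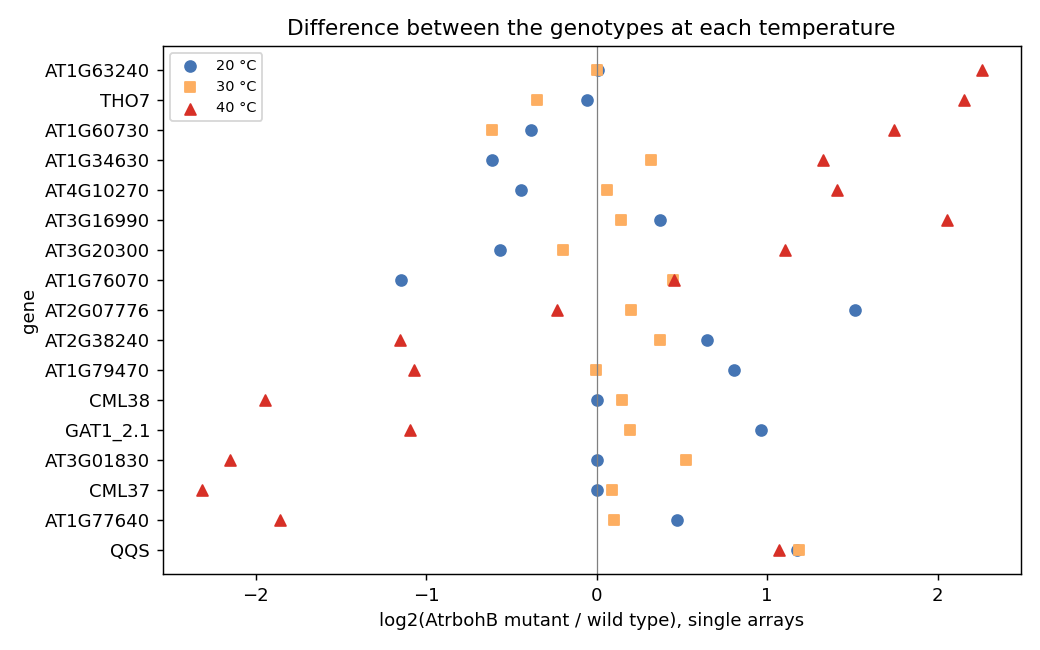
Log2 ratio of the AtrbohB mutant to wild type on single arrays at 20 °C (circles), 30 °C (squares) and 40 °C (triangles) for QQS and the 16 genes with the largest difference between the genotypes in their response to 40 °C. QQS lies between 1.07 and 1.19 at all temperatures, while the triangles of the other genes mostly lie apart from their circles and squares.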

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

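In this part, the splits of the arrays, the higher floor and log2(value + 16) were set before the result was seen. The other tests were chosen after it was seen. For the difference at 40 °C, 2 earlier tests were replaced because they could exclude nothing, and the test of stronger heating has much the same limit. For 7 of the 16 genes named for the difference in response, the change from 20 to 40 °C had opposite signs in the genotypes, and this difference was not tested. The response of the mutant minus that of wild type was 2.13 for AT1G60730, 1.94 for AT1G34630, 1.85 for AT4G10270, 1.68 for AT3G16990, 1.67 for AT3G20300, 1.61 for AT1G76070 and -1.80 for AT2G38240. With the higher floor the last 4 were 0.66, 0.39, 0.99 and -0.93, on log2(value + 16) AT1G60730 had 1.51 and AT4G10270 had 1.27, and AT3G16990 was at the floor in wild type at 40 °C. The medians of the scavenging enzymes and of the reference genes at 40 °C also had opposite signs, with differences of -0.13 and 0.23, not tested either. Control probe sets for spiked-in transcripts, which enter no comparison, were brighter than on the wild-type array at 20 °C by a mean log2 ratio of 0.50 on the wild-type array at 40 °C, 0.83 on the mutant array at 30 °C and 1.01 on the mutant array at 40 °C.

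Mitochondrial genes were higher at 40 °C in both genotypes. Priming of RNA without poly(A) tails, or DNA carried over, could lift all organelle sequences. By a like fold, the plastid genes would have risen as much, but their median was 0.31 (SD 0.49) against 4.22. This argues against a like fold only. A like amount of added signal gives a larger fold where the starting signal is low, so it is not excluded. At 20 °C nad6, for example, had signals of 23.6 in wild type and 20.1 in the mutant. Scaling of the arrays is argued against, as the lower of the medians under the other scalings was 4.15. Transcripts of the nuclear copy of mitochondrial DNA cannot be told apart from those of the organelle, as AT2G07777 rose by 5.23 and the other matches of the probes are not known here. A real effect of 40 °C on the level or the polyadenylation of mitochondrial transcripts therefore remains open.

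Mutant and wild type lay further apart at 40 °C. Of 1314 probe sets at least 2-fold higher at 30 °C, 80 were at least 2-fold lower in the mutant at 40 °C. Other probe sets of the same signal would give 8.05, which argues against weak labelling of the mutant array as the whole source. The spiked-in controls were brighter on the mutant array at 40 °C (1.01) than on the wild-type one (0.50), both against wild type at 20 °C. At 30 °C they were too (0.83 against 0.01), yet of the 1314 only 1 was at least 2-fold lower in the mutant there and 2 higher. The differences at 30 °C share arrays with the response that selects these probe sets. A part from weaker labelling at 40 °C therefore stays open, and the values at 30 °C give it no backing. Stronger heating of the mutant sample cannot be told apart by these values. The 379 probe sets lower at 40 than at 30 °C without a response at 30 °C had a median difference of -0.001. Of these, 5 were at least 2-fold lower in the mutant at 40 °C and 5 higher. The 1314 raised at 30 °C had a median of -0.159. The test set the median of the 379 against the spread of single probe sets (SD 0.388), so it could hardly exclude this cause. Handling or timing of single samples stays open too, because the SD of 0.350 between the genotypes at 40 °C comes from 1 array each and the mutant array is marked as a repeat. An effect of the mutation is the biological alternative, and the design holds it together with these.

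QQS was higher in the mutant at all temperatures. Noise near the floor is argued against, since its lowest signal was 3.02 times the floor. Exchanging mutant and wild type within temperatures gave as many probe sets 2-fold apart throughout in 2 of 4 assignments, the real one included, and 4 assignments are too few to exclude chance; the real value and the highest other were both 1. A difference between the seed lines other than the insertion cannot be told apart from the insertion itself, as the 1.14 rests on a single mutant line. For all probe sets, each of the 10 splits of the 6 arrays gave at least the real count of 0 calls (10 of 10), and the highest other count was 0. Any split reaches a count of 0, so this test could decide nothing, and 10 splits are too few for a share under 0.05. At an unadjusted limma p under 0.05 there were 735 probe sets in the real split. The other splits balanced within temperature had 548, 1005 and 894.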

How the results depend on the processing

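Under the other scalings, floors, filters and variance priors, the counts for the temperatures stayed within 1.5 times those reported, and the named genes of these comparisons kept their sign. Counting at 2-fold in single genotypes without a test gave 2197 probe sets in wild type and 1888 in the mutant at 40 against 20 °C, 2637 and 2874 at 30 against 20 °C, and 2939 and 3539 at 40 against 30 °C; a size rule differs from a test by construction. With an array left out, which leaves 1 residual degree of freedom and assumes that a lone array varies like the others, the counts ranged from 822 to 2800, from 2089 to 4340 and from 2783 to 6653 for these comparisons, and were 0 for mutant against wild type. For mutant against wild type, log2(value + 16), the filter on all 6 arrays and the 2-fold rule at all temperatures each gave 1 probe set. The adjusted p of QQS otherwise ran from 0.0976 to 1. Of the 7 list calls, 4 were left with the higher floor. With the estimated correlation 0 were left, but on 2 degrees of freedom that test could hardly call any list. The mean of the photosynthesis genes between genotypes turned to -0.0276 with quantile normalization, and the cause was not tested. The count of probe sets with a 4-fold difference in response, 19 as reported, was 6 with the higher floor, 6 with log2(value + 16), 8 with the filter on all 6 arrays and 1433 without a floor. Without a floor AT1G63240 had -0.42 and CML37 had 1.29. These genes have signals near the floor on some arrays, so their sizes rest on how low signals are treated.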

Other observations

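The groups in this part were formed after the data were seen, and only the correlation at its end was predicted before it was computed. Of 9 tau glutathione transferases, 9 fell at 30 against 20 °C, 7 of them also with quantile normalization or centring, with a median of -0.82 (camera adjusted p = 0.0014, and adjusted p = 0.932 with an estimated correlation). GSTU22 (-1.68), GSTU28 (-1.62) and GSTU16 (-1.36) were among them. At 40 against 20 °C GSTU20, the member with the highest mean signal, rose by 1.70. Of 8 autophagy genes, 5 rose at 30 °C, led by ATG8E (2.60) and ATG8H (1.36), with a median of 0.41 (camera adjusted p = 0.0211, and adjusted p = 0.932 with an estimated correlation).

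Of the gene families, 4 were called lower at 40 against 20 °C by camera, and 0 with an estimated correlation. Of 22 serine carboxypeptidase-like genes, 11 fell and 1 rose, with SCPL49 at -2.24 and scpl46 at -1.83 (camera adjusted p = 0.0070, and adjusted p = 0.932 with an estimated correlation). Of 20 TBL genes, a family of wall polysaccharide acetyltransferases, 7 fell and 1 rose, with TBL37 at -1.84 and TBL25 at -1.39 (camera adjusted p = 0.0076, and adjusted p = 0.932 with an estimated correlation). The rise was not called with quantile normalization or centring. Of 12 beta-glucosidases, 5 fell, among them BGLU25 (-1.05; camera adjusted p = 0.0339, and adjusted p = 0.932 with an estimated correlation). Of 10 PRA genes, which act in vesicle traffic, 5 fell, led by PRA8 (-1.40; camera adjusted p = 0.0394, and adjusted p = 0.932 with an estimated correlation). The SEC and VPS families, which also act in vesicle traffic, had medians of 0.28 and 0.30 and were not called.

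The 69 plastid genes had a median of 0.17 in the mutant against wild type, with no gene called (camera adjusted p = 9.65e-16, and adjusted p = 0.932 with an estimated correlation), and 0.10 with quantile normalization. By temperature the median was 0.25 at 20 °C, 0.28 at 30 °C and -0.04 at 40 °C, differences between single arrays that were not tested. Of 274 pseudogenes, 30 were higher at 40 against 20 °C and 0 lower, with 2 higher adjusted over the list alone (camera adjusted p = 0.0070, and adjusted p = 0.932 with an estimated correlation). With quantile normalization 16 of 257 were higher and 1 lower, and with centring 23 of 267 and 1. Of all probe sets 2456 of 18227 were higher, a larger share than among the pseudogenes. With the higher floor 92 pseudogenes were left, 15 higher and 1 lower. Most thus lie near the floor, where a fall cannot be seen. Ubiquitin ligases of the PUB family had a median of -0.19 in the mutant, with no member of 8 called (camera adjusted p = 0.0394, and adjusted p = 0.932 with an estimated correlation).

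A hypothesis, prompted by the named genes, is that genes which respond to 30 °C are those lower in the mutant at 40 °C. The mean response to 30 °C, from the arrays at 20 and 30 °C alone, had r = -0.174 with the difference between the genotypes at 40 °C across probe sets, which are not independent. Of the 1314 probe sets raised at least 2-fold at 30 °C, 80 were at least 2-fold lower in the mutant at 40 °C and 4 higher. The differences at 20 and 30 °C share arrays with the response that selects these probe sets, so unequal noise of those arrays could bias them. With that limit, r was 0.013 at 20 °C and 0.09 at 30 °C. Of the 1314, 8 were at least 2-fold lower and 5 higher at 20 °C, and 1 and 2 at 30 °C. Among the 80 were PUB22 (-1.18) and PUB23 (-1.60), ubiquitin ligases of stress signalling. With quantile normalization the numbers were 84 and 5, and with centring 76 and 5. This may reflect a role of AtrbohB in the level at 40 °C of transcripts raised at 30 °C. Stronger heating, handling or timing of single samples, or in part weaker labelling, may also give it. These arrays do not separate them.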
